A study of Mus musculus with 9 samples.

How the data were processed

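Samples, groups and the culture were taken from the series' labels. RNA of 9 Th17 cultures, 3 each from WT, SRG3 cKO and RORγt KO naive CD4 T cells, was hybridized to GeneChip arrays with 41345 probe sets. The values used were log2 probe set intensities as deposited in the series matrix, per the labels; how the authors corrected the background, summarized the probes and normalized the arrays is not given in the sources used here, and scanner files were not used here. Array medians were 7.12 to 7.14, and the quartiles of all values were 6.12 and 8.23. The labels call the arrays of a genotype biological replicates and give IL-6 at 30 µg/ml, a dose reported here as written there. No sample column was left unused (0).

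Of the probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none, and the latter 2 kinds were left out of the comparisons of genes. Symbols were brought up to date by gene ID (23328 matched) with the RefSeq table of assembly GRCm38.p6, which served for names and for which genes neighbour each other. For the 1082 genes with more than 1 probe set the probe set with the highest mean was used, giving 22180 genes. Results that need 1 item, among them the alternative without genes near the targeted loci, are not reported here. Transcripts of the Y-linked genes were present and Xist was low in all 9 arrays, so sex was not a covariate.

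Groups were compared with limma 3.58.1 in R 4.3.3 (linear models with moderated variances) in a single fit of all 9 arrays, and p-values were adjusted per comparison by the Benjamini-Hochberg method with a threshold of 0.05. A gene is said to rise, fall or change only where it passed that threshold. Folds are from log2 changes, SE is the standard error of the fit, and intervals are 95%. The numbers of the replicates were checked for pairing by the correlation of the deviations of arrays with the same number from their group means. Each number's correlation was 0.287, 0.186 and 0.116 for SRG3 cKO and WT, above that with other numbers, so the block value is given beside that comparison. For RORγt KO and WT it was 0.215, -0.00527 and 0.186, and for SRG3 cKO and RORγt KO 0.223, -0.00544 and 0.137, and these groups were not taken as paired.

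Before the data were examined, 27 gene lists were fixed: Th17 effector genes, Th17 transcription factors, Th1 and cytotoxic, Th2, Treg, Tfh, naive and homing, activation and T cell identity genes. They also held TGF-β response, IL-6 and STAT3 response, Swi/Snf subunit, histone modifier, cell cycle, p53 target and cyclin-dependent kinase inhibitor, BCL2 family, glycolysis, cholesterol and fatty acid synthesis, type I interferon response, circadian clock, chemokine receptor and integrin, and stress response genes. The others were markers of B cells and MHC class II, of myeloid cells, of CD8 T, NK and γδ T cells, of erythroid cells and of the X and Y chromosomes. Of 480 members 434 were measured. The 25 lists with at least 5 measured members were tested with camera (preset correlation 0.01), which compares a list with other genes, and again with an estimated correlation and with fry, which tests a list against no change. Erythroid genes (2 measured) and X-inactivation and Y-linked genes (4 measured) were not tested, and no member passed in any comparison. With the estimated correlation 0 of the 4 lists called in SRG3 cKO against WT, 3 of the 11 in RORγt KO against WT and 0 of the 13 in the direct comparison were called, and fry called 0, 11 and 9. In RORγt KO against WT the 11 lists of fry were not the 11 of camera. There fry called TGF-β response (fry adjusted p = 0.0455) and p53 target genes (0.0158), which camera did not. It did not call cell cycle (0.0808) or chemokine receptor and integrin genes (0.146).

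The groups, comparisons, tests, threshold, alternatives and the rule for naming genes were also set before the data were examined. Genes named were the 10 largest rises and falls among called genes in each comparison with WT, the 5 largest in the direct comparison, up to 4 members per list, and a fixed set of Th17-related genes. Any other gene is said to have been chosen after its values were seen. Alternatives covered normalization, centring, filters on dim probe sets, the choice of probe sets, the variance model, array weights, the arrays in the fit, the replicate block, leaving out each array, and fold thresholds. The replicate block in the 6 arrays of SRG3 cKO and WT and the fits without the arrays numbered 1 were chosen after seeing the data.

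The procedure was tested on simulated data made from the means and spread of these arrays, with 200 changed genes among 22180. In the simulated SRG3 cKO comparison 82.1%, 98.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 6 false calls (3.11% of calls). In the simulated RORγt KO comparison these were 76.1%, 98.5% and 100%, with 8 false calls (4.19%). A list shifted on purpose was called in both, and of the 25 lists 0 and 1 others were called. Genes were drawn independently in these simulated data. In the arrays the estimated correlation was 0.510 among B cell and MHC class II genes and 0.370 among glycolysis genes. The simulation thus does not show how often lists of correlated genes are called wrongly. Sharing of changes was set against 100 simulated data sets without effects. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.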

Results

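Gene expression was measured in T cells cultured under Th17-inducing conditions, that is, conditions under which naive CD4 T cells become T helper cells that secrete IL-17. Sorted naive CD4 T cells from mouse spleen were stimulated for 60 h with plate-bound antibodies against CD3 and CD28 (10 µg/ml each) in the presence of TGF-β1 (1 ng/ml), IL-6 and blocking antibodies against IL-4 and IFN-γ (2 µg/ml each). The cells came from wild-type (WT) mice, from SRG3 conditional knockout (SRG3 cKO) mice, and from RORγt knockout (RORγt KO) mice, with 3 arrays per genotype and 9 in all. SRG3 is the product of Smarcc1 and a core subunit of the Swi/Snf chromatin remodelling complex, and RORγt is the transcription factor that directs Th17 differentiation. The comparisons asked what the loss of either protein did to expression in these cultures and how far the changes were shared. Array medians lay between 7.12 and 7.14 on the log2 scale, and 22180 named genes were compared. On the first principal component (28.8% of the variance) WT array 1 lay at -1.38, against -10.5 and -11.8 for the other WT arrays, and RORγt KO array 3 at 3.22, against 9.82 and 11.97 for the others of its group. SRG3 cKO array 1 lay at 3.98, against -3.27 and -2.06 for the others of its group. The labels call the arrays of a genotype biological replicates without stating whether they came from separate mice or cultures, so p-values measure the spread between these arrays.

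Smarcc1 expression fell 3.15-fold in SRG3 cKO cells (log2 change -1.65, SE 0.09, limma adjusted p = 0.000207, n = 3 per group). Its level was 10.13, 10.32 and 10.39 in the WT arrays, 8.47, 8.79 and 8.62 in the SRG3 cKO arrays, and 10.12, 10.04 and 10.19 in the RORγt KO arrays. Of the 25 measured genes for Swi/Snf subunits, Smarcc1 was the only gene that passed the test in SRG3 cKO cells, and none passed it in RORγt KO cells. The RORγt KO labels were not checked in this way.

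**Figure D1:**
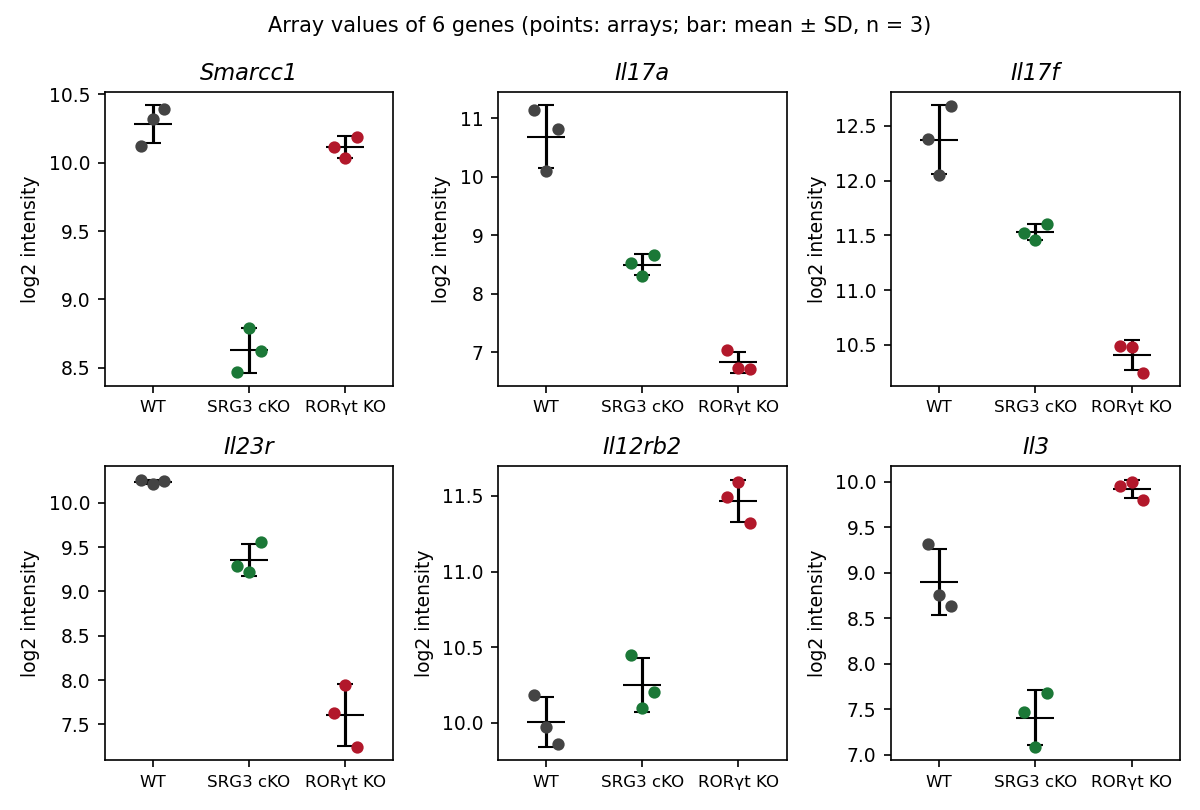
Log2 intensity (vertical axes) of Smarcc1, Il17a, Il17f, Il23r, Il12rb2 and Il3 in the WT, SRG3 cKO and RORγt KO arrays (horizontal axes). Points are arrays and bars give the mean and SD of 3 arrays; the vertical axes do not start at 0. Il17a averaged 10.69 in WT, 8.50 in SRG3 cKO and 6.83 in RORγt KO arrays.

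In SRG3 cKO cells the Th17 cytokine genes Il17a and Il17f were lower than in WT cells. Il17a, which encodes IL-17A, fell 4.56-fold (log2 change -2.19, SE 0.22, adjusted p = 0.00478, n = 3 per group), and Il17f, for the related cytokine IL-17F, fell 1.79-fold (-0.84, SE 0.14, adjusted p = 0.0361). Il23r, the receptor subunit for IL-23, fell 1.85-fold (-0.88, SE 0.15, adjusted p = 0.0451). Il3, a haematopoietic growth factor gene, fell 2.81-fold (-1.49, SE 0.18, adjusted p = 0.0127), and Nedd4, which encodes a ubiquitin ligase, rose 2.35-fold (1.24, SE 0.09, adjusted p = 0.000664). In all, 116 of 22180 genes changed, 62 higher and 54 lower, with a median absolute log2 change of 0.42. Of these, 1 rose and 4 fell at least 2-fold. SRG3 cKO and WT arrays of the same number were weakly correlated, and the labels state no pairing. With the number as a block in the fit of all 9 arrays, 195 genes changed, 125 higher and 70 lower. In a fit of the 6 SRG3 cKO and WT arrays alone 32 genes changed with the block, 16 higher and 16 lower, and 13 without it. Without WT array 1, 2 or 3 the count was 87, 28 or 23, without SRG3 cKO array 1, 2 or 3 it was 18, 43 or 22. Without RORγt KO array 1, 2 or 3, which enter through the shared estimate of the spread, it was 51, 77 or 64.

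Of the 20 Th17 effector genes, 5 fell in SRG3 cKO cells (Il17a, Il17f, Il23r, Il22 and Cd5l) and none rose, with 9 lower when adjusted over the list alone. As a group they lay lower than other genes (median log2 change -0.11, camera adjusted p = 0.000832), with an adjusted p = 0.466 with an estimated correlation. Cd5l, which encodes a regulator of lipid metabolism in Th17 cells, fell by 0.77 on the log2 scale (SE 0.08, adjusted p = 0.00614). Il22 fell by 0.51 (SE 0.07, adjusted p = 0.0216), but its probe set averaged within the lowest 0.585% of probe sets, near the floor of the array. The cytokine gene Csf2 was at -0.69 (SE 0.20, adjusted p = 0.225, or 0.0264 with the replicate block). Il9 at -0.73 (95% confidence interval -1.07 to -0.38), Ccl20 at -0.29 (-0.53 to -0.06) and Tmem176b at -0.16 (-0.29 to -0.03), the last chosen after its value was seen, were lower when adjusted over the list alone but not over all genes. Il21 at 0.22 (0.03 to 0.41) and Il10 at -0.11 (-0.48 to 0.26) did not pass. The IL-1 receptor gene Il1r1 was at -0.03 (-0.22 to 0.17) and the chemokine receptor gene Ccr6 at 0.02 (-0.11 to 0.15). Il17a and Smarcc1 were among the 10 of 32 named called genes that passed the test whichever of the 9 arrays was left out. Il17f did not pass in 8 of those 9 fits (range over all alternatives -1.0 to -0.69) and Il23r in 7 (-0.99 to -0.82), and Il23r had an adjusted p = 0.0552 with the replicate block. Over all 20 alternatives Smarcc1 always passed, and Il17a did not pass in 2.

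Of 19 genes for transcription factors of Th17 cells, 1 rose in SRG3 cKO cells and none fell: Ikzf3, which encodes the zinc-finger protein Aiolos, at 0.33 (SE 0.06, adjusted p = 0.0488, or 0.0661 with the replicate block). Ikzf3 did not pass in any of the 9 fits that left out 1 array, nor in 16 of all 20 alternatives (range 0.23 to 0.37). The list lay higher than other genes (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00751, or adjusted p = 0.466 with an estimated correlation). Irf4 was at 0.27 (adjusted p = 0.0847, or 0.0426 with the block), and Rora at 0.22, Batf at 0.08, Maf at -0.07 and Ahr at -0.29 did not pass. Genes that define other T helper fates did not pass the test either, with log2 changes of 0.11 for Foxp3, -0.24 for Tbx21, 0.11 for Gata3, 0.03 for Ifng and -0.09 for Bcl6.

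Genes for naive T cells and lymph node homing lay higher in SRG3 cKO cells as a group (camera adjusted p = 0.000715, or adjusted p = 0.466 with an estimated correlation). None of the 15 measured passed over all genes, and 8 were higher when adjusted over the list alone, among them Dapl1 at 0.48 (adjusted p = 0.0467 with the replicate block), Nsg2 at 0.25 and Foxo1 at 0.21. T cell identity genes behaved alike (14 measured, none past the threshold, 3 higher adjusted over the list alone, camera adjusted p = 0.00635 and adjusted p = 0.466 with an estimated correlation), with Thy1 at 0.27 and Cd3g at 0.23. Calls of lists changed with single arrays. Without WT array 2 the camera adjusted p was 0.0510 for the identity genes and 0.0670 for the transcription factors, and without SRG3 cKO array 1 it was 0.0886 for the identity genes.

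The other lists were not called in SRG3 cKO against WT cells, and few of their members passed. Th1 and cytotoxic genes had 1 that rose, Il18r1, and 1 that fell, Ccl3, of 21 (camera adjusted p = 0.557), Treg genes 1 that rose, Gpr83, of 21 (0.12), Th2 genes 1 that fell, Il3, of 14 (0.879), and Tfh genes none of 15 (0.656). Activation genes had 2 that fell, Cd44 and Tnfsf11, of 18 (0.656), and TGF-β response genes 1, Ldlrad4, of 15 (0.616). Chemokine receptor and integrin genes had 1 that rose, Itgav, and 1 that fell, Itgal, of 22 (0.82). P53 target genes had 1 that rose, Trp53inp1, of 19 (0.607), glycolysis genes 1 that rose, Aldoc, of 17 (0.0753), and Swi/Snf subunits Smarcc1 alone of 25 (0.95). None passed among IL-6 and STAT3 response (13, camera adjusted p = 0.656), histone modifier (23, 0.0649), cell cycle (26, 0.245), BCL2 family (13, 0.679), cholesterol and fatty acid synthesis (18, 0.937), type I interferon response (19, 0.366), circadian clock (12, 0.528) and stress response genes (15, 0.927). With the replicate block Ezh1 of the histone modifier genes (0.32, adjusted p = 0.0324), Izumo1r (0.44, 0.0324) and Tnfrsf9 (0.66, 0.0389) of the Treg genes, Cxcr3 of the Th1 genes (-0.32, 0.0180) and Crtam of the activation genes (-0.37, 0.0380) passed as well. The median and mean differed in sign for Th2 (0.01 and -0.07), Swi/Snf (0.01 and -0.05), TGF-β response (0.00 and -0.04), cholesterol synthesis genes (0.00 and -0.02). They also did for p53 target (-0.01 and 0.07), stress response (-0.00 and 0.03) and myeloid genes (-0.00 and 0.01). For activation genes the median and mean were above 0 while the test pointed down. Histone modifier genes were called without WT array 2 (camera adjusted p = 0.00454), SRG3 cKO array 3 (0.0276) or RORγt KO array 3 (0.0497), cell cycle genes without WT array 1 (0.0424), and glycolysis genes without WT array 1 (0.00222) or SRG3 cKO array 2 (0.0120).

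Ccn1, a matrix-associated signalling protein gene, fell by 1.04 in SRG3 cKO cells (SE 0.09, adjusted p = 0.00259), the chemokine gene Ccl3 by 0.99 (SE 0.12, adjusted p = 0.0128) and the inhibitory receptor gene Lilrb4a by 0.87 (adjusted p = 0.0443). Farp1 fell by 0.85 (adjusted p = 0.00192), and Tnfsf11, which encodes the cytokine RANKL, by 0.80 (adjusted p = 0.00192). The adhesion genes Cd44 (-0.36, adjusted p = 0.0488) and Itgal (-0.26, adjusted p = 0.0474) fell as well, as did Ldlrad4, an inhibitor of TGF-β signalling (-0.51, adjusted p = 0.0242). After Nedd4 the largest rises were those of Sdcbp2 (0.97, adjusted p = 0.0143), the microRNA gene Mir29a (0.96, adjusted p = 0.0378) and the p53 target Trp53inp1 (0.75, adjusted p = 0.0288). They were followed by Nckap1 (0.69), the Treg-associated receptor gene Gpr83 (0.69), the sestrin gene Sesn3 (0.68, adjusted p = 0.00319), the IL-18 receptor gene Il18r1 (0.63, adjusted p = 0.00375), S100a6 (0.62) and Ahcyl2 (0.61). Aldoc, a glycolytic aldolase gene, rose by 0.54 (adjusted p = 0.0463) and the integrin gene Itgav by 0.32 (adjusted p = 0.0216). Of the 9 fits that left out 1 array, Lilrb4a (range over all alternatives -1.0 to -0.68), Cd44 (-0.41 to -0.29) and Itgal (-0.29 to -0.24) passed in none. Aldoc did not pass in 8 of these fits, and Mir29a, Trp53inp1 and S100a6 did not pass in 7.

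In RORγt KO cells Il17a, Il23r and Il17f fell further than in SRG3 cKO cells, as the direct comparison below tests. Il17a fell 14.5-fold (log2 change -3.85, SE 0.22, limma adjusted p = 0.000143, n = 3 per group), Il23r 6.2-fold (-2.63, SE 0.15, adjusted p = 0.000143) and Il17f 3.91-fold (-1.97, SE 0.14, adjusted p = 0.000213). The Il17a level in RORγt KO cells, 6.83, lay below the median of all probe sets (7.13), and background was not measured here, so its fold is that of the intensities. Il1r1 fell 2.63-fold (-1.40, SE 0.09, adjusted p = 0.000143) and Furin, which encodes a proprotein convertase, 2.57-fold (-1.36, SE 0.08, adjusted p = 0.000143). The largest rise was that of Il12rb2, the IL-12 receptor subunit characteristic of Th1 cells, at 2.75-fold (1.46, SE 0.11, adjusted p = 0.000382). In all, 230 genes changed, 154 higher and 76 lower, with a median absolute log2 change of 0.40, and 3 rose and 7 fell at least 2-fold. Without WT array 1, 2 or 3 the count was 322, 45 or 65, without RORγt KO array 1, 2 or 3 it was 46, 47 or 165, and without SRG3 cKO array 1, 2 or 3 it was 153, 130 or 119.

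Of the 20 Th17 effector genes, 10 fell in RORγt KO cells and none rose (13 lower and 2 higher adjusted over the list alone). The list lay lower than other genes (median log2 change -0.53, camera adjusted p = 3.46e-14, or adjusted p = 0.0282 with an estimated correlation). Besides those named, the fallers were Il9 (-1.14, SE 0.15, adjusted p = 0.0129), the chemokine gene Cxcl3 (-0.91, SE 0.16, adjusted p = 0.0331), Ccr6 (-0.63, SE 0.06, adjusted p = 0.00135), Cd5l (-0.54, adjusted p = 0.0212) and Il22 (-0.51, adjusted p = 0.0144, the dim probe set). The RORγt KO levels of Il9 (5.94) and Cxcl3 (5.63) lay below the 25th percentile of all values (6.12), so their changes are those of dim intensities. Csf2 was at -0.68 (adjusted p = 0.187), Il10 at 0.65 (adjusted p = 0.127), Ccl20 at -0.18 and Il21 at 0.00, none of which passed. Of the 52 named called genes, 18 passed whichever array was left out, among them Il17a, Il17f, Il23r, Il1r1, Furin, Ccr6 and Il12rb2. Of genes named here and below, Gzmb, Nt5e, Ccr7, Hif1a, Egr2 and Itgal did not pass in 8 of the 9 fits that left out 1 array, and Cxcl3, Il3, Rora, Socs3 and Gbp3 did not in 7.

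**Figure D2:**
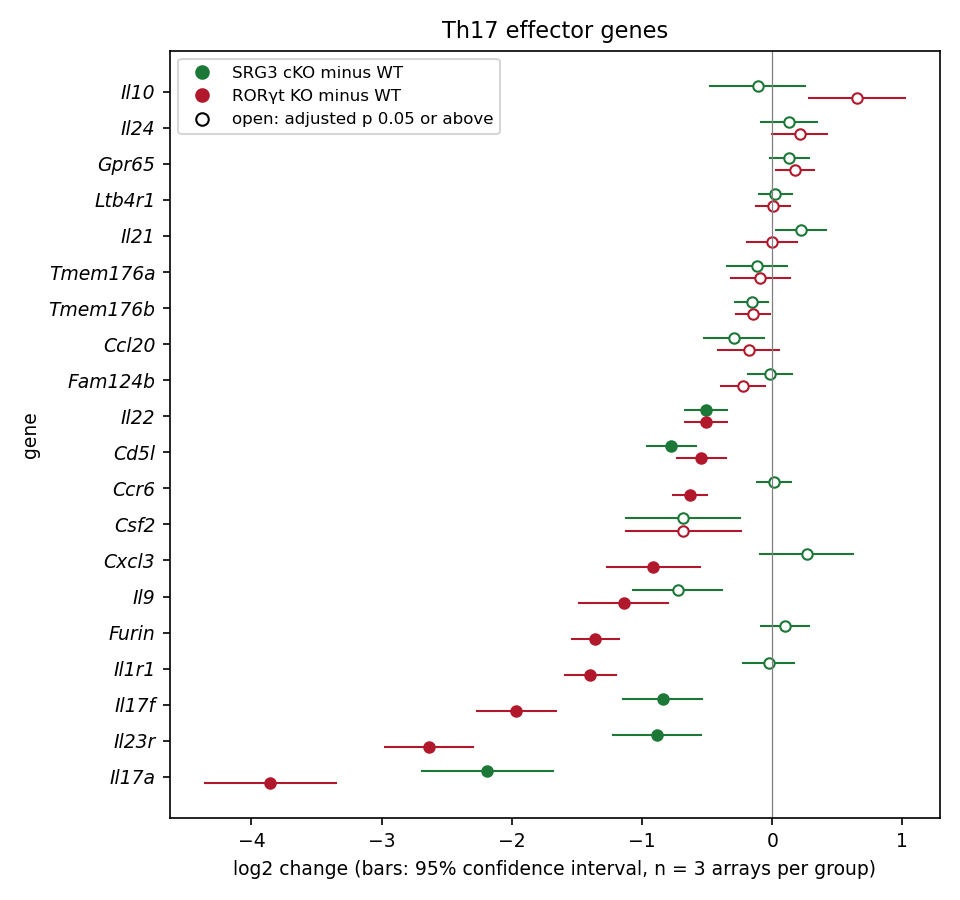
Log2 change (horizontal axis) of the 20 Th17 effector genes (vertical axis) in SRG3 cKO and RORγt KO against WT arrays. Bars are 95% confidence intervals from 3 arrays per group, and filled points passed the test. Il1r1, Furin and Ccr6 fell in RORγt KO cells and lay at -0.03, 0.10 and 0.02 in SRG3 cKO cells.

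Among the transcription factor genes, Ahr rose by 0.66 (SE 0.08, adjusted p = 0.00603), Rora by 0.36 (adjusted p = 0.05) and Hif1a by 0.26 (adjusted p = 0.0421) in RORγt KO cells, and none of the 19 fell. The list lay higher (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00844, or adjusted p = 0.247 with an estimated correlation). Batf at -0.25, Maf at 0.12 and Irf4 at 0.08 did not pass.

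Some genes of other T helper cell states rose in RORγt KO cells. Of 21 Th1 and cytotoxic genes, 3 rose: Il12rb2, Gzmb, for the cytotoxic protease granzyme B (0.77, adjusted p = 0.05), and Nkg7, for a granule protein (0.48, adjusted p = 0.0187). Il12rb1, the IL-12 and IL-23 receptor subunit gene, fell (-0.34, adjusted p = 0.0220). The list lay higher than other genes (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000989), with an adjusted p = 0.0519 with an estimated correlation. The Th1 genes Tbx21 (0.04) and Ifng (0.01) did not pass. Of 21 Treg genes, 3 rose, namely the ecto-nucleotidase gene Nt5e (1.16, SE 0.19, adjusted p = 0.0267), Tnfrsf9 (0.80, adjusted p = 0.0273) and Tigit (0.72, adjusted p = 0.0140), and none fell (7 higher adjusted over the list alone). The Treg list lay higher (camera adjusted p = 6.06e-07, or adjusted p = 0.0937 with an estimated correlation), while Foxp3 was at 0.31 (adjusted p = 0.138). Of 14 Th2 genes, 3 rose (Il3 at 1.02, Penk at 0.47 and Nfil3 at 0.37) and none fell (6 higher and 1 lower adjusted over the list alone). The Th2 list lay higher (camera adjusted p = 8.80e-05, or adjusted p = 0.0282 with an estimated correlation), with Gata3 at 0.22 (adjusted p = 0.222), not past the threshold. Of 15 Tfh genes 1 rose, Tnfsf8 (0.55, adjusted p = 0.0153), Bcl6 was at -0.23, and the list was not called (camera adjusted p = 0.703).

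Genes of naive T cells rose in part. Of 15, Il7r, the IL-7 receptor gene (0.95, SE 0.09, adjusted p = 0.00135), Ccr7, the lymph node homing receptor gene (0.66, adjusted p = 0.05), and Igfbp4 (0.50, adjusted p = 0.0123) rose, and Id3 fell (-0.45, adjusted p = 0.0308). The list lay higher (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000305, or adjusted p = 0.134 with an estimated correlation). Of 18 activation genes, Tnf (-0.82, SE 0.08, adjusted p = 0.00135), Crtam (-0.62, adjusted p = 0.0250) and Egr2 (-0.29, adjusted p = 0.0436) fell and none rose (4 lower adjusted over the list alone, camera adjusted p = 0.00119, or adjusted p = 0.0519 with an estimated correlation). Of 13 IL-6 and STAT3 response genes, Il10ra (0.87, adjusted p = 0.0185), Socs3, the feedback inhibitor of IL-6 signalling (0.54, adjusted p = 0.0317), and Il21r (0.35, adjusted p = 0.0202) rose and none fell. That list lay higher (7 higher adjusted over the list alone, camera adjusted p = 0.000289, or adjusted p = 0.0813 with an estimated correlation).

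Type I interferon response genes lay higher in RORγt KO cells (17 of 19 above 0, median log2 change 0.07, camera adjusted p = 9.83e-05, or adjusted p = 0.0282 with an estimated correlation), with 1 past the threshold, Gbp3 (0.48, adjusted p = 0.0318), and 4 higher adjusted over the list alone. Cell cycle genes lay lower by a small amount (22 of 26 not above 0, median -0.08, camera adjusted p = 0.000271, or adjusted p = 0.302 with an estimated correlation), with none past the threshold. Of 22 chemokine receptor and integrin genes, the 2 called members fell, Itga3 (-0.90, SE 0.06, adjusted p = 0.000143) and Itgal (-0.26, adjusted p = 0.0312). The list as a whole lay higher (median 0.11, 6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00947, or adjusted p = 0.143 with an estimated correlation). Both of these genes encode integrin α chains. Of the other largest changes in RORγt KO cells, Ctla2a (0.95, adjusted p = 0.0299) and Ctla2b (0.87, adjusted p = 0.0212), which encode cysteine protease inhibitors, Neb, for the muscle protein nebulin (0.93, SE 0.08, adjusted p = 0.000788), and Mctp2 (0.91, adjusted p = 0.0299) rose. Galnt3, for a glycosyltransferase, fell (-0.77, SE 0.06, adjusted p = 0.000391). Neb and Galnt3 passed whichever array was left out, and Ctla2a did not pass in 7 of those 9 fits. In the BCL2 family the anti-apoptotic gene Bcl2l1 fell (-0.35, adjusted p = 0.01) and the pro-apoptotic gene Bcl2l11 rose (0.70, adjusted p = 0.0140).

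Markers of other cells were measured beside these groups. B cell and MHC class II genes (camera adjusted p = 0.0539), myeloid genes (0.144) and CD8 T, NK and γδ T cell genes (0.394) were not called in RORγt KO against WT cells. Of the last list Klrd1, an NK receptor gene, rose (0.91, adjusted p = 0.0202). In SRG3 cKO against WT cells the camera adjusted p of these lists was 0.774, 0.950 and 0.366, with no member past the threshold. In RORγt KO cells the B cell list was called as higher without WT array 2 (camera adjusted p = 0.000115) or RORγt KO array 2 (0.0113), and in SRG3 cKO cells as lower without WT array 3 (0.00235).

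The remaining lists were not called by camera in RORγt KO against WT cells, though fry called the TGF-β response and p53 target genes. TGF-β response genes had 1 that fell, Id2, of 15 (-0.32, camera adjusted p = 0.324), p53 target genes 1 that rose, Trp53inp1, of 19 (camera adjusted p = 0.29), and the BCL2 family the 2 genes above of 13 (0.703). None passed among T cell identity (14, 0.212), Swi/Snf subunit (25, 0.212), histone modifier (23, 0.292), glycolysis (17, 0.0539), cholesterol and fatty acid synthesis (18, 0.139), circadian clock (12, 0.195) and stress response genes (15, 0.504). Glycolysis genes were called without WT array 1 (camera adjusted p = 0.00164), SRG3 cKO array 1 (0.0481) or RORγt KO array 3 (0.0283), and cholesterol synthesis genes without WT array 1 (0.0198) or 3 (0.00455).

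The direct comparison tested whether expression differed between SRG3 cKO and RORγt KO cells. The labels call only the SRG3 knockout conditional, so a difference between these groups need not stem from the lost proteins alone. SRG3 cKO cells kept higher expression of Il23r (3.36-fold, log2 difference 1.75, SE 0.15, limma adjusted p = 0.000679, n = 3 per group), Il17a (3.18-fold, 1.67, SE 0.22, adjusted p = 0.00736). Il17f, chosen for this comparison after its value was seen, was higher too (1.12, SE 0.14, adjusted p = 0.0044). They also kept higher Furin (2.75-fold, 1.46, SE 0.08, adjusted p = 0.000118), Il1r1 (2.58-fold, 1.37, SE 0.09, adjusted p = 0.000165) and Cxcl3 (1.18, SE 0.16, adjusted p = 0.00763). The RORγt KO level of Cxcl3, 5.63, lay below the 25th percentile of all values (6.12). SRG3 cKO cells had lower Il3 (5.70-fold, -2.51, SE 0.18, adjusted p = 0.000352), Smarcc1 (-1.49, adjusted p = 0.000164), Nt5e (-1.39, adjusted p = 0.00782), Lilrb4a (-1.34, adjusted p = 0.00249) and Ccl3 (-1.23, adjusted p = 0.00128). The 10 genes other than Il17f passed whichever array was left out, and Il17f was not checked in this way. In all 283 genes differed, 132 higher and 151 lower in SRG3 cKO cells. Without SRG3 cKO array 1, 2 or 3 the count was 153, 146 or 150, and without RORγt KO array 1 or 2 it was 138 or 157.

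By list, 7 of the 20 Th17 effector genes were higher in SRG3 cKO than in RORγt KO cells and none was lower (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.59e-06, or adjusted p = 0.108 with an estimated correlation). Of 21 Th1 and cytotoxic genes, 2 were higher and 7 lower (3 and 10 adjusted over the list alone, camera adjusted p = 8.62e-05, or adjusted p = 0.0651 with an estimated correlation). The lower genes included Ccl3, Ccl4, Ccl5, Gzmb and Il12rb2, chosen after their values were seen. In this comparison 13 of 25 lists were called, 6 higher and 7 lower, of which none was called with an estimated correlation and 9 by fry. Markers of other cells were among the 13, both lower in SRG3 cKO cells. They were B cell and MHC class II genes (camera adjusted p = 0.0137, or adjusted p = 0.459 with an estimated correlation) and CD8 T, NK and γδ T cell genes (camera adjusted p = 0.0449, or adjusted p = 0.183 with an estimated correlation). Klrd1 was the only member of these 2 lists past the threshold.

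Members of the other lists called in the direct comparison are named as chosen after their values were seen. Lower in SRG3 cKO cells were Th2 (2 lower of 14, Il3 and Penk, camera adjusted p = 0.000475, or adjusted p = 0.0651 with an estimated correlation) and Treg (1 higher, Gpr83, and 2 lower, Nt5e and Tigit, of 21, 0.00388, or adjusted p = 0.283 with an estimated correlation) genes. Lower too were IL-6 and STAT3 response (3 lower of 13, among them Il10ra and Il21r, 0.00388, or adjusted p = 0.139 with an estimated correlation) and type I interferon response genes (2 lower of 19, Gbp3 and Igtp, 0.0097, or adjusted p = 0.108 with an estimated correlation). Higher were histone modifier (none of 23 past the threshold, camera adjusted p = 0.00161, or adjusted p = 0.183 with an estimated correlation) and activation (4 higher, among them Tnf and Egr2, and 1 lower, Tnfsf11, of 18, 0.0214, or adjusted p = 0.138 with an estimated correlation) genes. Higher too were circadian clock (1 of 12, Arntl, 0.0224, or adjusted p = 0.138 with an estimated correlation), cell cycle (none of 26, 0.0369, or adjusted p = 0.564 with an estimated correlation) and T cell identity genes (none of 14, 0.0496, or adjusted p = 0.357 with an estimated correlation). Some of these calls rested on single arrays. The identity list had a camera adjusted p of 0.0516 without WT array 2, 0.0523 without WT array 3, 0.358 without SRG3 cKO array 1, 0.0863 without RORγt KO array 2 and 0.156 without RORγt KO array 3. The cell cycle list had 0.0882 or 0.0740 without SRG3 cKO array 2 or 3 and 0.618 without RORγt KO array 2, and the clock list 0.0649 without SRG3 cKO array 3 and 0.0591 without RORγt KO array 3. The B cell list had 0.0940 without RORγt KO array 1. The CD8 T, NK and γδ T cell list had 0.0586 or 0.0523 without WT array 1 or 3, 0.102 or 0.0652 without SRG3 cKO array 1 or 3, and 0.139 or 0.0528 without RORγt KO array 2 or 3. The chemokine receptor and integrin list, not called (0.0853), had 0.0491 without WT array 1 and 0.0339 without SRG3 cKO array 1.

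Of all genes, 26 changed the same way in both deficiencies and 1 changed in opposite ways. The 16 genes lower in both included Il17a, Il23r, Il17f, Igfbp7 (-0.61 in SRG3 cKO and -0.70 in RORγt KO cells) and Cd5l. The 10 genes higher in both included Trp53inp1 (0.75 and 0.78), Sesn3 (0.68 and 0.80), Samhd1, which encodes a nucleotide triphosphate hydrolase (0.50 and 0.67), Pik3r5 (0.44 and 0.39) and Npc2 (0.31 and 0.39). When 1 array was left out, Pik3r5 did not pass in 8 of the 9 fits in either comparison, and Npc2 did not in 7 in SRG3 cKO cells. Il3 fell in SRG3 cKO cells and rose in RORγt KO cells. Independent lists of these lengths would share 0.185 genes lower in both, 0.430 higher in both and 0.587 opposite, numbers that do not allow for the shared WT arrays. Without WT array 1, 2 or 3 the number changed the same way was 29, 4 or 6, without SRG3 cKO array 1, 2 or 3 it was 4, 9 or 7, and without RORγt KO array 1, 2 or 3 it was 7, 10 or 15. With the replicate block it was 53.

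**Figure D3:**
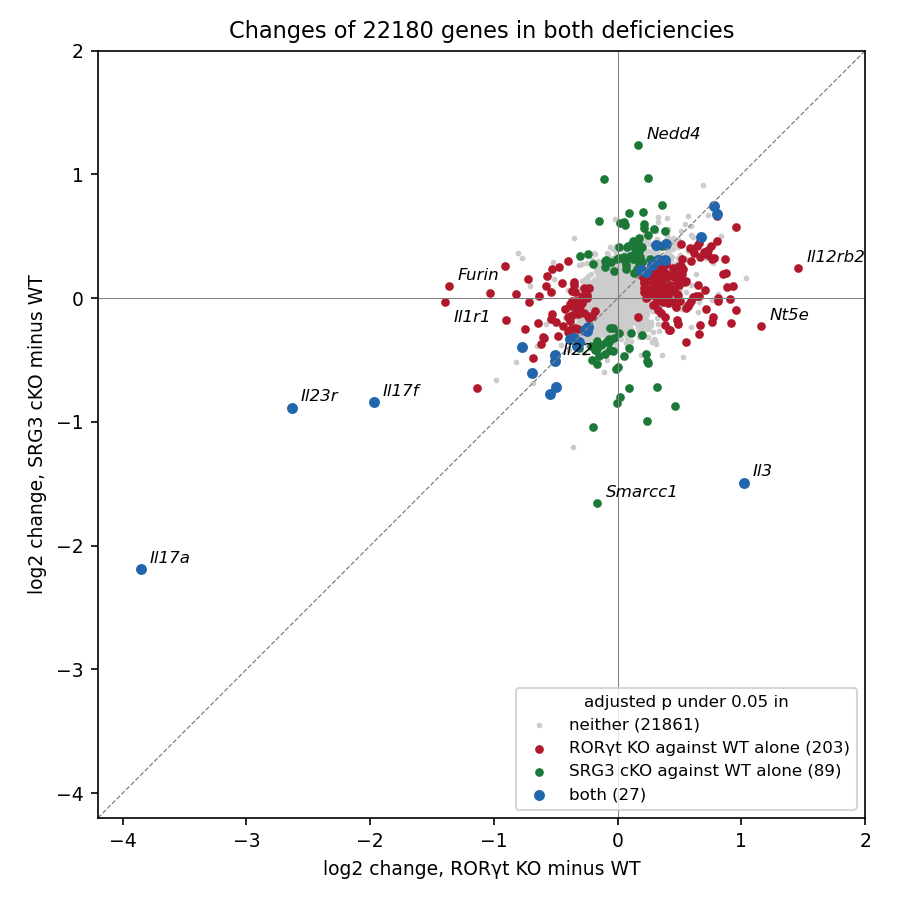
Log2 change in SRG3 cKO against WT arrays (vertical axis) and in RORγt KO against WT arrays (horizontal axis). Each point is 1 of 22180 genes, coloured by the comparison in which it passed the test, and the dashed line marks equal changes. Il17a, Il23r and Il17f fell in both, and Il3 lay at -1.49 and 1.02.

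Across all genes the changes in the 2 deficiencies had a Pearson r of 0.491, against 0.5 in the simulated data sets (range 0.473 to 0.522), so r was no higher than shared WT arrays alone gave. Genes are not independent replicates, and no p is given. The covariance was 0.00584 against a simulated 0.00262 (highest 0.00280), a difference of 0.00322. Without WT array 1 it was 0.01. The simulation draws genes independently and leaves out any correlation between arrays of the same number. The same WT arrays stand on both sides of these counts, so how much of the excess comes from the shared controls is open. With a different WT array on each side, the covariance ranged from 0.000423 to 0.00684 over the 6 pairs of WT arrays (mean 0.00297), and was lowest in pairs that held WT array 1.

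The genes that changed in RORγt KO cells were compared gene by gene in SRG3 cKO cells. Of all genes, called or not, 67.9% had log2 estimates of the same sign in both deficiencies, against a mean of 66.7% (65.5% to 67.5%) in the 100 simulated data sets with shared WT arrays and no effects. Of the 76 that fell, 55 also lay below WT in SRG3 cKO cells and 16 were called there, while 37 differed from RORγt KO in the direct comparison in the direction of WT. Of the 154 that rose, 119 lay above WT in SRG3 cKO cells, 10 were called higher and 1 lower there, and 67 differed from RORγt KO in the direction of WT. The median log2 change of the fallers was -0.40 in RORγt KO and -0.13 in SRG3 cKO cells, and that of the risers 0.41 and 0.12. Of the 54 genes that fell in SRG3 cKO cells, 26 differed from RORγt KO cells in which they lay nearer to or above WT, and of the 62 that rose, 27 differed in the opposite sense. Because the genes of each set were chosen on 1 comparison, their change in that comparison is overstated relative to the other. The shared WT arrays can also favour the same sign in genes chosen so. No share was simulated for chosen genes, so 55 of 76 and 119 of 154 cannot be judged against the 66.7% of all genes.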

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

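No test in this part was chosen after its result was seen, but Il3 was picked by its results. Il3, which encodes a growth factor of haematopoietic cells, was singled out because the deficiencies moved it in opposite ways. A gene picked so is bound to differ in the direct comparison, which is therefore no separate support. SRG3 cKO minus RORγt KO was -2.51 on the log2 scale (SE 0.18, 5.70-fold, limma adjusted p = 0.000352, n = 3 per group), with -1.49 in SRG3 cKO and 1.02 in RORγt KO cells against WT. The direct difference passed whichever array was left out, the fall did not pass without SRG3 cKO array 1, and the rise against WT did not pass in 7 of the 9 fits. No biological explanation was tested.

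Probe sets that do not name 1 gene were outside the comparisons above, and a signal appeared among these 17824. By limma with the same threshold, 16 differed between SRG3 cKO and WT (16 higher), 51 between RORγt KO and WT (43 higher and 8 lower), of which 7 name several genes, and 78 between SRG3 cKO and RORγt KO (32 higher and 46 lower). Their transcripts were not analysed here.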

How the results depend on the processing

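The fits without the arrays numbered 1, and the replicate block in 6 arrays, were chosen after seeing the data. Of the values of called named genes over all alternatives, 1401 stayed past the threshold and 466 did not, and none reversed. Smarcc1, Il17a, Nedd4 and Tnfsf11 in SRG3 cKO cells, and Il17a, Il17f, Il23r, Il1r1, Furin and Il12rb2 in RORγt KO cells, passed in every fit that left out 1 array. Over all 20 alternatives, in SRG3 cKO cells Smarcc1 always passed, Il17a did not pass in 2, and Nedd4 and Tnfsf11 did not in 1 each. In RORγt KO cells Il17f did not pass in 1 of the 20, and the others named always passed. With quantile normalization, array weights, centring, the other variance model or other probe sets the gene counts stayed within 1.5 times.

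For SRG3 cKO against WT the count of 116 became 196 among genes above the median probe set, where fewer genes are tested, 13 with only the 6 arrays compared, 195 with the replicate block, 32 with the block in those 6 arrays, 28 at 1.5-fold and 5 at 2-fold. For RORγt KO against WT the count of 230 became 348 above the median, 43 with 6 arrays, 374 with the block, 64 at 1.5-fold and 10 at 2-fold. For SRG3 cKO against RORγt KO the count of 283 became 142 with 6 arrays, 79 at 1.5-fold and 19 at 2-fold. The 26 genes changed the same way in both became 41 above the median, 3 with 6 arrays and 53 with the block. Leaving out 1 array gave 18 to 87, 45 to 322, 138 to 261 and 4 to 29, with fewer arrays in the fit. Without all arrays numbered 1 these were 1, 25, 16 and 0 by limma. Where the cause is not named it was not tested.

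Gene lists called fell from 4 to 0 in SRG3 cKO against WT with the estimated correlation and to 0 with fry, from 11 to 3 in RORγt KO against WT and from 13 to 0 in the direct comparison with the estimated correlation.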

Other observations

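Among the tests of this part, those of cytotoxic cells and of undeleted cells were chosen only after the results were seen. Segments of the T cell receptor α chain were measured one by one and were chosen after their values were seen. Trav12-2 was at 0.88 (limma adjusted p = 0.00023) and Trav7-4 at -0.71 (adjusted p = 0.000788) in RORγt KO against WT cells, and at 0.09 and -0.03, not past the threshold, in SRG3 cKO cells. The other 3 segments measured did not pass. Probes of such similar segments can share signal.

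Genes near a targeted gene can keep variants of the strain in which it was altered, which may change their signal. Of the 261 genes within 10 Mb of Smarcc1 none was called in SRG3 cKO against WT cells, against 114 of 21729 elsewhere (Fisher's exact test, two-sided, p = 0.648; 2480 of all genes had an unadjusted limma p under 0.05). Smarcc1 itself was left out of these counts, and the 114 are the other called genes with a known position. With 0.525% called elsewhere, few calls can be expected among 261 genes, so this test says little about such variants.

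Of the 10 splits of the 6 arrays compared, 1, the real split, called as many genes in each comparison, 116, 230 and 283, and the highest of the others called 1, 0 and 0, and 10 splits are too few for a share under 0.05.

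Il12rb2, Gzmb and Nkg7 rose in RORγt KO cells, which CD8 T or NK cells could bring, although the cultures began with sorted naive CD4 T cells, a sort that would remove them. The CD8 T cell genes Cd8a and Cd8b1 had a median log2 change of -0.0251, and their upper 95% bounds, 0.05 and 0.16, lay under the 0.48 of Nkg7. These CD8 T cell genes thus did not rise by as much. How far admixed CD8 T cells would raise each gene was not measured, so a small admixture is not excluded. The NK cell genes Klrb1c, Ncr1 and Klrk1 had a median of 0.0470, but all 3 lay below the median of all probe sets. The NK receptor gene Klrd1 rose, from a probe set that was dim as well (percentile 26.5 of all probe sets), so NK cells stay open. The state of the CD4 T cells themselves was not tested.

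In SRG3 cKO cells Il17a fell while Furin, Il1r1 and Ccr6 did not pass, and cells that escaped deletion might hide a loss of the RORγt KO kind. The share of such cells was first taken from the group means of Il17a (16.2%). The median gap between the measured and predicted changes of the 75 other genes that fell in RORγt KO cells was then 0.223 (0.162 to 0.270). At the highest share the Il17a arrays allow (29.8%) it was 0.166 (0.0864 to 0.218), where a gap above 0.2 had been asked for at both. These intervals come from 2000 bootstrap draws of the 75 genes, not of arrays, and genes are not independent replicates. They therefore leave out the spread between arrays. Smarcc1 itself, which fell 3.15-fold, was not used to set a share. At the share of 29.8%, 40 of the 75 lay above and 7 below their prediction beyond the 95% interval. Furin was at 0.10 against -0.81, Il1r1 at -0.03 against -0.82 and Ccr6 at 0.02 against -0.41, but Il17f at -0.84 against -1.07 and Il23r at -0.88 against -1.28. The genes were chosen for their fall in RORγt KO cells, which overstates the predictions. The gap asked for was not reached at both shares, so dilution stays open for the 75 genes as a set. The 95% intervals of Furin (-0.08 to 0.28), Il1r1 (-0.22 to 0.17) and Ccr6 (-0.11 to 0.15) lay above their predictions. These genes were singled out because they had not passed in SRG3 cKO cells, so this is no separate evidence against dilution. Whether SRG3 loss affects only part of the genes that need RORγt is a hypothesis to be tested in sorted deleted cells.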
